A study of Mus musculus with 17 samples.

How the data were processed

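The deposited table holds linear intensity values for 45101 probe sets on 17 arrays, which per the labels are robust multi-array average (RMA) values computed by the authors from the raw scans in GenePattern. The version and whether all arrays were normalized together are not given in the sources used here. Values run from 4.058 to 27170 and array medians from 59.03 to 63.17. The log2 of each value was taken without a pseudocount, and no further normalization was applied. A second SpRA Foxp3- array is not analysed here. None of the 17 arrays was left out, and no columns held identical values.

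Probe sets were named from the platform's gene table: 34958 have 1 gene symbol, 932 have several and 9211 have none, and the last 2 kinds were not used. Each of the 18194 genes is represented by its probe set with the highest mean log2 over all 17 arrays, probe sets of the cross-hybridizing kind being passed over where another exists. The text says where another probe set of a named gene moved the other way. A gene was tested where its value lay above the array median on at least 2 arrays, which left 11846 genes in the co-culture, 12062 in the memory experiment and 11432 in both.

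The 11 comparisons and 2 interaction terms, the gene lists, the alternatives and the genes always named were fixed before the data were examined. One limma 3.58.1 model (R 4.3.3) was fitted per experiment with 1 coefficient per group, followed by empirical Bayes, contrasts and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p threshold of 0.05. The mean Foxp3+ over Foxp3- difference weighs the 3 cultures equally. In the co-culture model 5 residual degrees of freedom were joined by a prior of 3.19, and in the memory model 4 by a prior of 2.59.

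The labels number the arrays, and whether the numbers pair them was checked by correlating the residuals of arrays with the same number after group means were removed. Correlations were 0.45 to 0.75 over 10 pairs of co-culture groups, where groups of 2 arrays give the same value for both numbers, and 0.65 to 0.94 for the 3 numbers of the memory groups, so the numbers do pair the arrays. The model without a number term (the unpaired fit) was kept as designed, and the model with the number as a block (the paired fit), listed among the alternatives from the start, is printed beside it, with 4 and 2 residual degrees of freedom and priors of 5.56 and 7.23.

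Both fits were tested on 5 simulations of 200 changed genes, with the gene means, number effects and residual spread of the real arrays. For RA in memory cells the unpaired fit recovered 51.2% of changes of log2 2 and 0.0% of log2 1, and the paired fit 100.0% and 99.6%. For RA in Foxp3+ cells the values were 91.2% and 23.6% unpaired and 100.0% and 92.8% paired, and for the mean Foxp3+ difference 99.6% and 77.2% against 100.0% for both sizes. False calls were 0.00%, 0.00% and 0.41% of calls unpaired and 6.95%, 6.91% and 7.72% paired. The paired fit, favoured by built-in number effects, is still too liberal (nominal rate 5%).

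The 23 gene lists hold 422 entries, 377 of them with a named probe set, and cover regulatory T cells, genes lower in Foxp3-expressing cells, retinoid metabolism, homing, cytokines, Th1, Th2, Th17, TGF-beta, interferon, cell cycle, naive and memory cells, co-stimulation, glycolysis, sterols, early response, housekeeping, T cell identity, sex and markers of B, CD8 and NK, dendritic and erythroid cells. The erythroid list had too few measured genes and was not tested. Each of the other 22 was tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a comparison. For each list the genes passing over all genes tested were counted, and those passing when adjusted over the list alone.

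Genes named by rule in each comparison are the 10 largest rises and falls that passed with replicates that do not overlap, up to 4 members of each list that passed, and a set of genes always named (among them Foxp3, Rarb, Cyp26b1, Dhrs3, Ccr9, Itga4, Itgb7, Ifng, Il4, Il21, Il17a, Il2, Il10, Tbx21, Gata3, Smad3, Ctla4 and Il2ra), in either fit. The text gives 422 of the 667 results this names, picked from them after the values were seen, with every tested gene of the always-named kind kept. 1 gene of that set is not reported here.

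Correlations between effects are across genes, which are not independent, and effects that share arrays were compared with simulated noise. Alternatives were quantile normalization, median-centring, no filter, a stricter filter at the 60th percentile, log2 of the value plus 32, the mean of all probe sets, trended and robust variances, one fit over all arrays, a fit to the compared groups alone, the number as a block and each array left out in turn. Alternatives added later were both memory arrays numbered 3 left out, each setting repeated with the block, genes on X and Y left out, and a joint fit for RA in memory against co-culture cells. Group labels were exchanged to count calls by chance.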

Results

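Transcript levels of sorted mouse CD4 T cells were measured on 17 Affymetrix arrays from a pair of culture experiments. In the first, CD4 T cells without Foxp3, the transcription factor of regulatory T cells, came from spleens of Foxp3/GFP reporter mice. They were cultured for 5 days with dendritic cells (DC) of the spleen (Sp-DC), DC of the lamina propria (LP-DC), or Sp-DC plus 100 nM retinoic acid (RA), the active form of vitamin A. Transforming growth factor beta (TGF-beta), IL-2 and an antibody to CD3 were present in all 3 cultures, and the cells were then sorted into Foxp3+ and Foxp3- by GFP. Each of these 6 groups has 2 arrays, except the Foxp3- cells of the culture with RA, which has 1 array. In the second experiment, memory CD4 cells (CD44hi, CD62L-, CD25-) were cultured for 48 hours with naive cells and TGF-beta, with or without 100 nM RA, and sorted again by a congenic marker (3 arrays per group). Each array holds cells of 3 pooled mice.

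The array numbers within each experiment pair the samples, so results are given from a pair of limma fits. The unpaired fit is the planned one, and the paired fit adds the array number as a block. Values in parentheses after a gene are log2 differences ± standard error. They come from the paired fit where the gene passed an adjusted p of 0.05 there, and from the unpaired fit where it passed in neither. Every gene that passed unpaired also passed paired. A gene is said to rise, fall or change only where it passed in at least the paired fit, and genes that passed in both are named as such. The paired fit gave more false calls than its nominal rate on simulated data, so genes that passed in both fits carry more weight. List tests are those of the unpaired fit with a preset correlation between genes unless said otherwise. With a correlation estimated from the data, no list passed in the paired fit in any comparison. Differences of a gene whose lower group lies more than 1 log2 unit under the array median on every array are lower bounds. This concerns 9 of the values given as changed. They are Ccr9 with RA in memory and in Foxp3+ cells and in LP-DC over Sp-DC plus RA, Foxp3+ cells, Ntn4 in memory cells, Abi3bp, Capsl and Serpinb1a under LP-DC in Foxp3+ cells, and Cxcr6 and Tjp1 in the sort with LP-DC. Where a group has 1 array, as Foxp3- cells with RA do, its spread is taken from the other groups.

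RA in memory cells. RA raised Itga4, Ccr9, Dhrs3 and Cyp26b1 in CD44hi memory cells and lowered the cytokines Il4, Il9, Il10 and Il21 (3 arrays in each group). Itga4, the integrin subunit that pairs with beta 7 in gut homing, rose 16.7-fold (4.06 ± 0.14, adjusted p = 9.88e-07 paired and 0.00258 unpaired). Ccr9, a chemokine receptor of T cells that home to the gut, rose (3.33 ± 0.28, adjusted p = 0.000216 paired and 0.0491 unpaired), from 3.78 to 4.82 without RA, which is near background. Il10, which encodes an inhibitory cytokine, fell 7.14-fold (-2.84 ± 0.13, adjusted p = 5.97e-06 paired and 0.00918 unpaired), and Il4, the defining Th2 cytokine, fell 3.98-fold (-1.99 ± 0.15, adjusted p = 0.000119 paired and 0.0605 unpaired). Foxp3 averaged 8.38 (SD 0.69) with RA and 7.69 (SD 0.59) without on the log2 scale and did not pass (0.69 ± 0.44, adjusted p = 0.0925 paired and 1 unpaired). Il2 did not pass the signal filter in these cells.

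**Figure D1:**
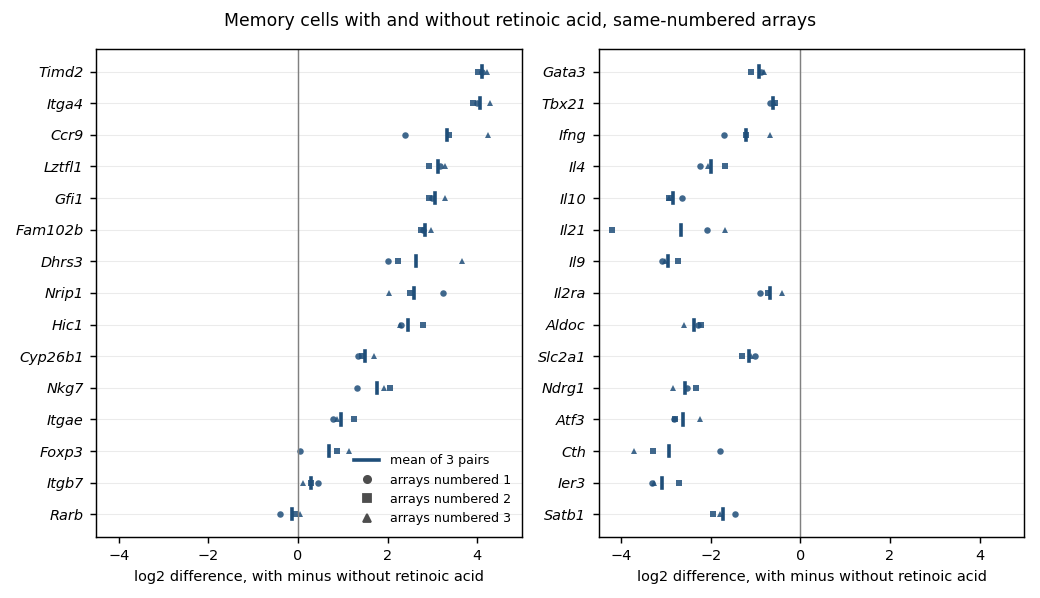
Log2 difference with minus without RA in memory CD4 cells for 30 genes (x axis), 1 marker per same-number pair of arrays and a bar at the mean of the 3 pairs. Itga4 (4.06) and Ccr9 (3.33) lie at the top and Il10 (-2.84) among the falls.

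The unpaired fit called 10 genes, 5 higher and 5 lower, and 495 had an unadjusted p under 0.05. The paired fit called 596 genes, 314 higher and 282 lower, and 226 of them differed at least 2-fold. The 10 that passed in both are Itga4, Ccr9, Timd2 (4.11 ± 0.13), a surface protein of the Tim family, Gfi1 (3.06 ± 0.13), a transcriptional repressor, and Nipal1 (1.97 ± 0.13) among the rises, and Il10, Map3k20 (-2.22 ± 0.13), a stress kinase, Aldoc (-2.37 ± 0.14), an aldolase, Ndrg1 (-2.57 ± 0.14) and Ier3 (-3.09 ± 0.16) among the falls. Other large rises in the paired fit were Lztfl1 (3.12 ± 0.13), Fam102b (2.83 ± 0.13), Slc2a2 (2.76 ± 0.25), a glucose transporter, and Ntn4 (2.45 ± 0.18), and other large falls were Pkib (-3.23 ± 0.21), Il9 (-2.95 ± 0.13), Cth (-2.93 ± 0.30), an enzyme that makes cysteine, Alpk2 (-2.72 ± 0.31) and Mt1 (-2.49 ± 0.13), a metallothionein. Leaving out Memory 2 or MemoryRA 1 left 0 unpaired calls (limma, 330 and 354 with an unadjusted p under 0.05), MemoryRA 2 left 1, Memory 1 left 2 and MemoryRA 3 left 4, while in the paired fit 208 were called without Memory 3 or MemoryRA 3, 206 of them among the 596. With quantile normalization 62.5% of the unpaired calls were rises, against 50.0%.

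Retinoid metabolism and retinoic acid receptors had 6 of 16 measured genes up in the paired fit and 10 that did not pass, with 0 passing unpaired (adjusted over the list alone, 6 rose and 2 fell paired and 4 rose unpaired). They include Dhrs3 (2.63 ± 0.27), an enzyme that returns retinal to retinol, Cyp26b1 (1.49 ± 0.13), which degrades RA, Nrip1 (2.59 ± 0.20), a nuclear receptor co-repressor, Hic1 (2.46 ± 0.15), a transcriptional repressor, and Asb2 (0.89 ± 0.14), while the RA receptor Rarb (-0.14 ± 0.35) did not pass. The list moved up (adjusted p = 0.00158), but adjusted p = 0.235 with an estimated correlation. Of 23 homing receptors and adhesion genes, 4 rose and 5 fell in the paired fit and 2 rose unpaired, and the list test did not pass (adjusted p = 0.217). Itgae (0.97 ± 0.14), the CD103 integrin subunit, rose, whereas Itgb7 (0.28 ± 0.22), the beta 7 partner of Itga4, did not pass. TGF-beta response genes had 3 of 16 up in the paired fit and 0 unpaired (6 and 0 over the list alone). These were Itgae, Tgfbr2 (0.69 ± 0.13), where another probe set moved the other way, and Id2 (0.55 ± 0.13). The list gave adjusted p = 0.00158, and adjusted p = 0.165 with an estimated correlation. Smad3 (0.22 ± 0.16), a mediator of TGF-beta signalling, did not pass.

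The Th2 programme had 8 of 13 genes down in the paired fit and 1 in the unpaired fit (9 and 8 over the list alone), with a median of -0.76. Gata3 (-0.93 ± 0.13), the Th2 transcription factor, and Nfil3 (-1.14 ± 0.13) fell beside Il4, Il9 and Il10. The list gave adjusted p = 6.56e-15, and adjusted p = 0.0689 with an estimated correlation. Effector cytokines and chemokines had 7 of 18 down and 3 up in the paired fit and 1 down unpaired, among them Il21 (-2.66 ± 0.38), a cytokine of helper cells, and Ifng (-1.20 ± 0.19), the Th1 cytokine (list adjusted p = 0.00101, adjusted p = 0.0853 with an estimated correlation). The Th1 programme had 2 up and 3 down of 12 in the paired fit, with Fasl (1.32 ± 0.17) up and Tbx21 (-0.61 ± 0.13), the Th1 transcription factor, down, and its test did not pass (adjusted p = 0.0996). The Th17 programme had 3 of 12 down in the paired fit and 0 unpaired, and Il17a (-0.20 ± 0.21) did not pass (list adjusted p = 0.0044, adjusted p = 0.158 with an estimated correlation). Genes lower in Foxp3-expressing T cells had 5 of 11 down in the paired fit and 0 unpaired, with Satb1 (-1.73 ± 0.14), a chromatin organizer, Il4, Il21 and Ifng among them (adjusted p = 2.93e-06, adjusted p = 0.0689 with an estimated correlation). Of the regulatory T cell signature 6 rose and 5 fell among 26 in the paired fit, and its test did not pass (adjusted p = 0.391). Il2ra (-0.68 ± 0.14), the alpha chain of the IL-2 receptor, fell and Ctla4 (-0.04 ± 1.46) did not pass.

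Glycolysis and lactate genes had 8 of 14 down in the paired fit and 0 in the unpaired fit (11 and 5 over the list alone), with a median of -0.56. Tpi1 (-0.80 ± 0.13), Aldoa (-0.89 ± 0.13) and the glucose transporters Slc2a1 (-1.14 ± 0.13) and Slc2a3 (-1.21 ± 0.13) are examples (list adjusted p = 4.74e-14, adjusted p = 0.0689 with an estimated correlation). Early response and stress genes had 2 up and 6 down of 17 in the paired fit and 0 unpaired, with Fos (2.06 ± 0.18) and Jun (1.20 ± 0.13) up and Atf3 (-2.61 ± 0.15) and Ddit4 (-1.83 ± 0.16), an inhibitor of mTORC1, down (adjusted p = 0.00397, adjusted p = 0.112 with an estimated correlation). Of 6 markers of CD8 T and NK cells, Nkg7 (1.76 ± 0.16), Gzmk (0.88 ± 0.16) and Klrd1 (0.87 ± 0.14) rose in the paired fit and 0 unpaired (adjusted p = 0.00899, adjusted p = 0.162 with an estimated correlation). Sterol and fatty acid genes had 1 up and 3 down of 20 in the paired fit, interferon response genes 2 of 16 up, and co-stimulatory and inhibitory receptors 1 up and 1 down of 19. Their estimated-correlation adjusted p = 0.218, 0.218 and 0.13. Cell cycle (26 genes), housekeeping (10), DC markers (9) and sex genes (4) had 0 calls in both fits (limma, 1898 genes with an unadjusted p under 0.05 in the paired fit). Median and mean of the cell cycle list are 0.01 and -0.03, of the housekeeping list 0.01 and -0.08, and of the DC markers 0.03 and -0.07, with the test downward in all of them. In the paired fit B cell markers had 1 up and 1 down of 6, T cell identity genes 1 up and 1 down of 10, and genes of naive and memory T cells 1 of 14 down.

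Foxp3+ over Foxp3- cells, mean of the 3 cultures. Cells sorted as Foxp3+ carried more transcripts of the regulatory T cell signature and less Cxcr6, Gzma and Klrd1 (6 Foxp3+ and 5 Foxp3- arrays). Gpr83 (2.49 ± 0.23, adjusted p = 0.000742 paired and 0.0164 unpaired) and Izumo1r (1.56 ± 0.09, adjusted p = 9.01e-05 paired and 0.00378 unpaired), surface receptors of regulatory T cells, rose in both fits. Cxcr6 (-3.56 ± 0.47, adjusted p = 0.00243 paired and 0.0257 unpaired), a chemokine receptor of tissue T cells, and Gzma (-2.86 ± 0.47, adjusted p = 0.00698 paired and 0.0482 unpaired), which encodes granzyme A, fell in both fits. The Foxp3 probe set itself lay near background on all 11 arrays (log2 3.88 to 4.53), so Foxp3 was not tested in this experiment, and nor were Il21 and Il2.

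**Figure D2:**
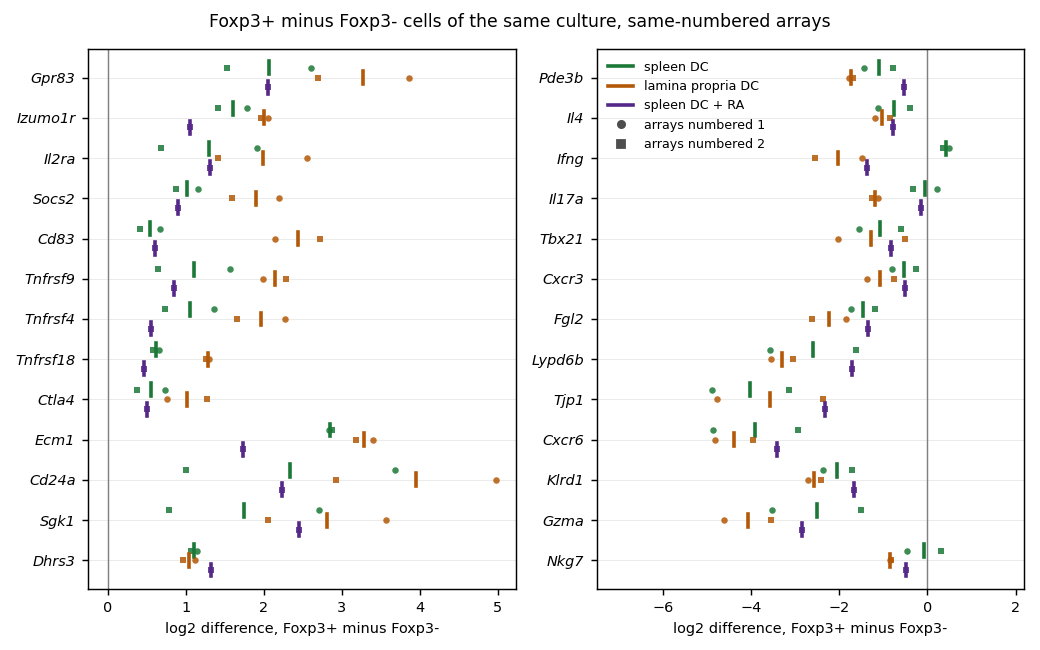
Log2 difference Foxp3+ minus Foxp3- for 26 genes (x axis) in the cultures with Sp-DC, LP-DC and Sp-DC plus RA, 1 marker per same-number pair of arrays, with 1 pair in the culture with RA. In the LP-DC culture the mean is 3.28 for Gpr83 and -4.39 for Cxcr6.

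Unpaired, 109 genes passed, 59 higher and 50 lower, with 54 at least 2-fold. The paired fit called 568, 312 higher and 256 lower, with 107 at least 2-fold. Because the groups are unequal, its log2 differences are not identical to those of the unpaired fit. Rises that passed in both fits were Cd24a (2.81 ± 0.36), Cpe (2.60 ± 0.41), Sgk1 (2.33 ± 0.28), a kinase, Enah (1.87 ± 0.12), an actin regulator, Stxbp6 (1.79 ± 0.25), Procr (1.73 ± 0.18), Ppm1l (1.68 ± 0.15), Dusp4 (1.81 ± 0.15), a MAP kinase phosphatase, and Cd81 (1.79 ± 0.19). Ecm1 (2.60 ± 0.09) rose in the paired fit. Falls that passed in both were Tjp1 (-3.20 ± 0.36), a tight-junction protein, Lypd6b (-2.49 ± 0.28), Klrd1 (-2.14 ± 0.15), St3gal6 (-2.10 ± 0.23), a sialyltransferase, the non-coding Mirt1 (-1.87 ± 0.21), Fgl2 (-1.61 ± 0.14) and Nebl (-1.54 ± 0.15), and Trgv1 (-2.24 ± 0.23) fell in the paired fit. The unpaired count dropped to 3 without Sp Foxp3- 1, 15 and 18 without LP Foxp3+ 2 or 1, 29 and 72 without LP Foxp3- 1 or 2, 41 without Sp Foxp3- 2, 45 without Sp Foxp3+ 1, and 66 and 67 without SpRA Foxp3+ 2 or 1. Median-centring gave 164, and the paired count was 329 without Sp Foxp3- 1.

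The regulatory T cell signature had 14 of 25 measured genes up in the paired fit, 5 in the unpaired fit and 0 down (18 and 11 over the list alone), with a median of 0.66. Beside Gpr83 and Izumo1r, Socs2 (1.29 ± 0.16), a suppressor of cytokine signalling, and Cd83 (1.18 ± 0.10) rose in both fits, while Il2ra (1.58 ± 0.26), Tnfrsf9 (1.29 ± 0.16), Tnfrsf4 (1.18 ± 0.12), Tnfrsf18 (0.74 ± 0.09) and Ctla4 (0.64 ± 0.13), an inhibitory receptor, rose in the paired fit only. The list gave adjusted p = 4.12e-21, and adjusted p = 0.0189 with an estimated correlation. Co-stimulatory and inhibitory receptors had 8 of 18 up in the paired fit and 0 unpaired (8 and 4 over the list alone), including Tnfrsf9, Tnfrsf4, Tnfrsf18 and Ctla4 (adjusted p = 0.000243, adjusted p = 0.171 with an estimated correlation). Of 6 markers of CD8 T and NK cells, Klrd1 and Gzma fell in both fits (adjusted p = 1.75e-05, adjusted p = 0.108 with an estimated correlation). Of 23 homing receptors and adhesion genes 1 fell unpaired, Cxcr6, and 3 paired. That list has a median of -0.03 and did not pass (adjusted p = 0.699). Early response genes moved up (median 0.13, adjusted p = 0.00649) and the cell cycle list down (median -0.14, adjusted p = 0.00798), with adjusted p = 0.458 and 0.646 for an estimated correlation.

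The Th1 programme had 3 of 12 down in the paired fit and 0 unpaired, with Tbx21 (-1.07 ± 0.20) and Cxcr3 (-0.74 ± 0.12), a Th1 chemokine receptor, among them (adjusted p = 0.00798, adjusted p = 0.458 with an estimated correlation). Ifng (-0.96 ± 0.41) did not pass. Of the Th2 and Th17 genes, Il4 (-0.85 ± 0.12), Il17a (-0.42 ± 0.10) and Ahr (-0.93 ± 0.12) fell and Il6st (0.56 ± 0.10) rose in the paired fit. Neither list test passed (adjusted p = 0.732 and 0.239), and Gata3 (0.30 ± 0.18) and Il10 (-0.17 ± 0.23) did not pass. Lta (1.21 ± 0.18), a cytokine of the TNF family, rose in both fits. Genes lower in Foxp3-expressing T cells had 2 of 11 down paired and 1 unpaired, with the phosphodiesterase Pde3b (-1.15 ± 0.13) in both (adjusted p = 0.00649, adjusted p = 0.151 with an estimated correlation). Within retinoid metabolism, Dhrs3 (1.05 ± 0.13) rose and Hic1 (-0.74 ± 0.11) fell in both fits, Cyp26b1 (0.34 ± 0.10) and Rarb (0.09 ± 0.27) did not pass, and the list did not pass (adjusted p = 0.45). In the TGF-beta response Tgfbr1 (0.50 ± 0.12) rose and Tgfbr2 (-0.69 ± 0.13) and Tgfbr3 (-0.97 ± 0.12) fell in the paired fit, the last with another probe set in the other direction. Smad3 (0.13 ± 0.16) did not pass, and the list has a median of 0.08, a mean of -0.04 and an upward test that did not pass (adjusted p = 0.691). The gut-homing genes Itga4 (0.43 ± 0.19), Itgb7 (0.01 ± 0.12) and Ccr9 (0.00 ± 0.39) did not pass, and 1 of the other probe sets of Ccr9 moved the other way.

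Foxp3+ over Foxp3- cells with LP-DC. The same signature was seen in the LP-DC culture alone (2 arrays in each group), where Enah (2.68 ± 0.20, adjusted p = 0.000225 paired and 0.00831 unpaired), Izumo1r (2.01 ± 0.14, adjusted p = 0.000211 paired and 0.00831 unpaired) and Cd83 (2.44 ± 0.15, adjusted p = 0.00018 paired and 0.0114 unpaired) rose and Fgl2 (-2.23 ± 0.22, adjusted p = 0.00123 paired and 0.0338 unpaired) fell in both fits. Large falls in the paired fit were Cxcr6 (-4.39 ± 0.75), Gzma (-4.08 ± 0.74), Tjp1 (-3.56 ± 0.57), Lypd6b (-3.28 ± 0.45) and Klrd1 (-2.56 ± 0.24). In all 16 genes passed unpaired, 12 higher and 4 lower, and 424 paired, 284 higher and 140 lower. Others in both fits included Gpr83 (3.28 ± 0.37), Dusp4 (3.17 ± 0.24), Efna5 (2.25 ± 0.17), a ligand of Eph receptors, Gnaq (1.81 ± 0.19), a G protein subunit, Slc44a1 (1.64 ± 0.17) and Tm4sf5 (1.63 ± 0.20) among the rises. The remaining falls in both were Rcbtb2 (-1.24 ± 0.12) and Rnf144a (-1.38 ± 0.17), where another probe set moved the other way, and a gene known only by a RIKEN name. Cd24a (3.95 ± 0.57), Myb (3.48 ± 0.56), a transcription factor of immature cells, and Ecm1 (3.29 ± 0.14) rose in the paired fit. Unpaired, 0 were called without either LP Foxp3+ array (limma, 556 and 490 with an unadjusted p under 0.05), and 2 and 3 without LP Foxp3- 1 or 2. Paired, 168 and 185 were called without LP Foxp3+ 1 or 2, and 178 without LP Foxp3- 1, of which 155, 169 and 151 are among the 424. Quantile normalization, median-centring and the mean of probe sets gave 48, 39 and 37 unpaired calls, and a fit to the compared groups alone gave 0 (limma, 771 with an unadjusted p under 0.05).

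The regulatory T cell signature had 15 of 25 up in the paired fit and 3 in the unpaired fit (18 and 13 over the list alone), with a median of 1.01 and Tnfrsf9 (2.14 ± 0.25), Il2ra (1.99 ± 0.41) and Ctla4 (1.01 ± 0.21) among them (adjusted p = 1.85e-21, and 0.0181 with an estimated correlation). CD8 T and NK markers had 3 of 6 down in the paired fit and 0 unpaired, including Cd8a (-1.26 ± 0.24), and the list passed both ways (adjusted p = 6.06e-09, and 0.0386 with an estimated correlation). Genes lower in Foxp3-expressing T cells had 3 of 11 down in the paired fit and 0 unpaired, Pde3b (-1.73 ± 0.21), Ifng (-2.03 ± 0.39) and Il4 (-1.02 ± 0.18) (adjusted p = 7.39e-05, and 0.0463 with an estimated correlation). The cell cycle list had a median of -0.36 and 0 calls among 26 genes in both fits (adjusted p = 7.91e-10, adjusted p = 0.254 with an estimated correlation). Il17a (-1.19 ± 0.16) fell and Dhrs3 (1.04 ± 0.21) rose in the paired fit. Tbx21 (-1.28 ± 0.48), Gata3 (0.61 ± 0.30), Il10 (-0.54 ± 0.37), Smad3 (0.43 ± 0.26), Cyp26b1 (-0.10 ± 0.15), Rarb (-0.26 ± 0.43), Itga4 (0.62 ± 0.31), Itgb7 (0.07 ± 0.19) and Ccr9 (-0.73 ± 0.62) did not pass.

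Foxp3+ over Foxp3- cells with Sp-DC. With Sp-DC (2 arrays in each group) Ecm1, Izumo1r and Gpr83 rose and Tjp1 (-4.02 ± 0.57, adjusted p = 0.0312) fell, in the paired fit. The unpaired fit called 0 genes (limma, 419 with an unadjusted p under 0.05), and the paired fit 66, 32 higher and 34 lower. Ecm1 (2.86 ± 0.14, adjusted p = 2.88e-05), Izumo1r (1.60 ± 0.14, adjusted p = 0.00479), Enah (1.70 ± 0.20), Gpr83 (2.07 ± 0.37), Cd81 (1.82 ± 0.30), Ppm1l (1.79 ± 0.24) and Procr (1.73 ± 0.29) rose. Lypd6b (-2.60 ± 0.45), St3gal6 (-2.29 ± 0.37), Klrd1 (-2.04 ± 0.24), Sytl2 (-1.68 ± 0.18), Cd93 (-1.64 ± 0.25) and Fgl2 (-1.47 ± 0.22) fell. The paired count dropped to 1 without Sp Foxp3- 1, 3 without Sp Foxp3- 2 and 7 without Sp Foxp3+ 1. It was 112 after quantile normalization and 10 with the mean of probe sets, and median-centring moved the share of rises from 48.5% to 61.5%. The regulatory T cell signature had 3 of 25 up in the paired fit and 0 unpaired, Tnfrsf4 (1.05 ± 0.19) among them (13 and 5 over the list alone), with a median of 0.56 (adjusted p = 6.35e-16, and 0.0362 with an estimated correlation). Dhrs3 (1.10 ± 0.25) passed only over its list. Il2ra (1.30 ± 0.48), Ctla4 (0.56 ± 0.26), Ifng (0.42 ± 0.66), Tbx21 (-1.08 ± 0.48), Il4 (-0.76 ± 0.38), Gata3 (0.32 ± 0.30), Il17a (-0.06 ± 0.18), Il10 (0.00 ± 0.37), Smad3 (0.24 ± 0.26), Itga4 (0.21 ± 0.31), Itgb7 (0.12 ± 0.19), Cyp26b1 (0.04 ± 0.15), Rarb (-0.02 ± 0.43) and Ccr9 (-0.13 ± 0.62), whose other probe sets moved the other way, did not pass.

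Foxp3+ over Foxp3- cells with Sp-DC and RA. With RA present, Csn2 (2.13 ± 0.21, adjusted p = 0.0118), a casein, Gda (1.92 ± 0.19, adjusted p = 0.0118), guanine deaminase, and Ecm1 (1.64 ± 0.17, adjusted p = 0.0135) rose in the paired fit (2 Foxp3+ arrays and 1 Foxp3- array). Unpaired there were 0 calls (limma, 198 with an unadjusted p under 0.05), and the paired fit these 3. The paired count was 0 without SpRA Foxp3+ 1 or 2 (limma, 409 and 1207 with an unadjusted p under 0.05) and 1 with the mean of probe sets. Unpaired, log2 of the value plus 32 gave 2 calls and a fit to all 17 arrays 1. The 25 genes of the regulatory T cell signature had a median of 0.16 unpaired and 0.32 paired. Il2ra (1.30 ± 0.58), Ctla4 (0.47 ± 0.32), Ifng (-1.26 ± 0.81), Tbx21 (-1.15 ± 0.58), Il4 (-0.48 ± 0.47), Gata3 (-0.02 ± 0.36), Il17a (0.01 ± 0.22), Il10 (0.02 ± 0.46), Smad3 (-0.27 ± 0.32), Dhrs3 (1.08 ± 0.30), Cyp26b1 (1.07 ± 0.19), Rarb (0.55 ± 0.53), Ccr9 (0.87 ± 0.76), Itga4 (0.47 ± 0.38) and Itgb7 (-0.17 ± 0.24) did not pass.

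RA over none with Sp-DC, Foxp3+ cells. In Foxp3+ cells RA raised Ccr9, Cyp26b1 and Dhrs3 and lowered Ifitm1, Ifitm2 and Ifitm3, interferon-induced membrane proteins (2 arrays in each group). Ccr9 rose (5.29 ± 0.40, adjusted p = 0.000215 paired and 0.0235 unpaired), from 3.91 and 4.16 without RA, which is near background. The RA-degrading enzyme Cyp26b1 rose 6.57-fold (2.72 ± 0.14, adjusted p = 1.65e-05 paired and 0.000507 unpaired), and Ifitm1 fell 21.6-fold (-4.43 ± 0.23, adjusted p = 1.65e-05 paired and 0.000714 unpaired). Unpaired, 12 genes passed, 11 higher and 1 lower, and 133 paired, 73 higher and 60 lower. Rises in both fits included Bex1 (3.48 ± 0.25), Gda (3.27 ± 0.15), Cracdl (2.95 ± 0.15), Lztfl1 (2.79 ± 0.13), Csn2 (2.59 ± 0.17), Dhrs3 (2.36 ± 0.21), Mmd (2.12 ± 0.14) and Asb2 (2.03 ± 0.14). Cttn (2.79 ± 0.27), the actin-binding cortactin, Tnfsf11 (2.52 ± 0.35), a TNF family cytokine, P2rx7 (2.46 ± 0.39), an ATP receptor, and Egr2 (2.19 ± 0.26) and Egr3 (2.33 ± 0.40), induced by T cell receptor signals, rose in the paired fit, with another probe set of Egr3 in the other direction. Paired falls were Ifitm3 (-3.96 ± 0.53), Ifitm2 (-2.32 ± 0.31), Endou (-3.30 ± 0.39), Lgals3 (-2.37 ± 0.26), galectin 3, S100a4 (-2.27 ± 0.32) and Tmcc3 (-2.08 ± 0.22). Unpaired calls were 8 without SpRA Foxp3+ 2, 6 without Sp Foxp3+ 2, 6 with a stricter filter, 20 over all 17 arrays and 3 from the compared groups alone. Paired calls were 61 and 48 without SpRA Foxp3+ 1 or 2 and 51 without Sp Foxp3+ 2, and median-centring moved the share of rises from 54.9% to 44.3%.

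**Figure D3:**
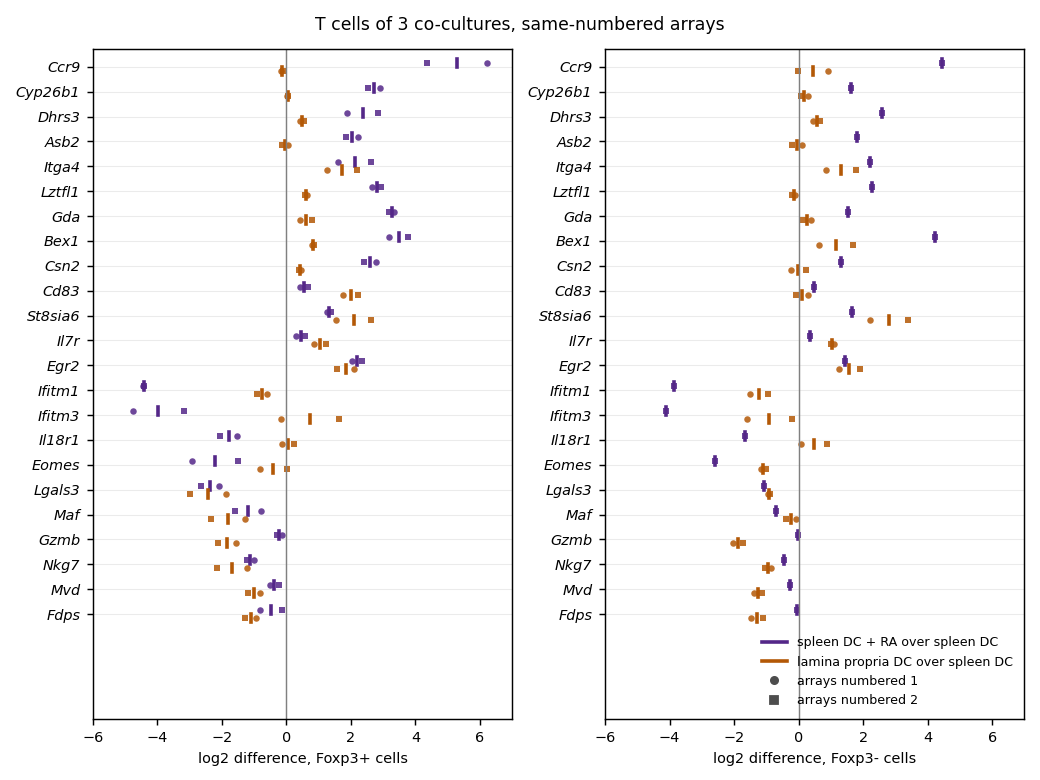
Log2 difference over Sp-DC alone (x axis) of Sp-DC plus RA (purple) and LP-DC (orange) for 23 genes, Foxp3+ cells at left and Foxp3- cells at right, 1 marker per same-number pair (1 pair for RA in Foxp3- cells). Ccr9 averages 5.29 with RA and -0.15 with LP-DC in Foxp3+ cells, while Itga4 averages 2.11 and 1.72.

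Retinoid metabolism genes had 4 of 14 up in the paired fit and 3 unpaired, Hic1 (0.92 ± 0.17) being the addition, with a median of 0.07 and a mean of 0.63 (adjusted p = 0.000152, adjusted p = 0.126 with an estimated correlation). The Th1 programme had 2 of 12 down in the paired fit and 0 unpaired, Eomes (-2.22 ± 0.26), a transcription factor, and Il18r1 (-1.79 ± 0.26) (adjusted p = 8.34e-05, adjusted p = 0.515 with an estimated correlation), while Tbx21 (-1.08 ± 0.48) and Ifng (-1.60 ± 0.66) did not pass. Of 23 homing genes Ccr9 rose in both fits and Itga4 (2.11 ± 0.26) in the paired fit, and Itgb7 (-0.04 ± 0.19) did not pass. Il6ra (-2.02 ± 0.25), Maf (-1.20 ± 0.22), a Th2 transcription factor, Klrd1 (-1.43 ± 0.24) and the interferon-induced Gbp2 (-1.13 ± 0.16) fell in the paired fit. Il4 (-0.03 ± 0.38), Gata3 (-0.11 ± 0.30), Il10 (-0.48 ± 0.37), Il17a (-0.02 ± 0.18), Ctla4 (-0.24 ± 0.26), Smad3 (0.39 ± 0.26), Rarb (0.16 ± 0.43) and Il2ra (0.09 ± 0.48), whose other probe set moved the other way, did not pass.

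LP-DC over Sp-DC, Foxp3+ cells. Without added RA, LP-DC raised Itga4 (1.72 ± 0.26, adjusted p = 0.0266) but not Ccr9 (-0.15 ± 0.62) in Foxp3+ cells (2 arrays in each group), 1 of the other probe sets of Ccr9 moving the other way. The unpaired fit called 0 genes (limma, 947 with an unadjusted p under 0.05), and the paired fit 215, 139 higher and 76 lower. Cd83 (2.00 ± 0.15, adjusted p = 0.00268), St8sia6 (2.09 ± 0.29), Abi3bp (2.76 ± 0.56), Lad1 (2.03 ± 0.40), Capsl (2.02 ± 0.33), Scin (1.82 ± 0.27), an actin-severing protein, Cpm (1.75 ± 0.36), Amigo2 (1.74 ± 0.31) and Egr2 (1.84 ± 0.26) rose. Serpinb1a (-2.97 ± 0.59), a protease inhibitor, Emilin2 (-2.66 ± 0.48), Lgals3 (-2.43 ± 0.26, adjusted p = 0.0124), Pik3ap1 (-2.19 ± 0.37), Ppp1r3b (-2.15 ± 0.42), Ctla2a (-2.11 ± 0.33), Ctla2b (-2.13 ± 0.43), Sbsn (-2.10 ± 0.37) and Endou (-1.96 ± 0.39) fell. The paired count was 2 without LP Foxp3+ 2, 3 without Sp Foxp3+ 2 and 451 without Sp Foxp3+ 1. It was 418 after quantile normalization and 36 with the mean of probe sets, and median-centring moved the share of rises from 64.7% to 54.6%.

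In the paired fit, sterol and fatty acid genes had 4 of 20 down, Lss (-1.24 ± 0.23), Fdps (-1.11 ± 0.22) and Mvd (-1.01 ± 0.16) of cholesterol synthesis among them, and Abca1 (1.25 ± 0.25), the cholesterol exporter, up, against 0 unpaired (adjusted p = 0.000934, adjusted p = 0.47 with an estimated correlation). Glycolysis genes had 1 of 13 down and a median of -0.41 (adjusted p = 1.1e-05, adjusted p = 0.405 with an estimated correlation). Interferon response genes had 1 of 17 up and a median of 0.50 (adjusted p = 0.00653, adjusted p = 0.491 with an estimated correlation). The Th1 programme had 1 of 12 down, Gzmb (-1.84 ± 0.20), encoding granzyme B, and the Th2 programme 2 of 11, Maf (-1.83 ± 0.22) and Nfil3 (-1.68 ± 0.29) (adjusted p = 0.000141 and 0.0219, adjusted p = 0.405 for both with an estimated correlation). Nkg7 (-1.70 ± 0.23) and Id2 (-1.65 ± 0.30) fell and Penk (1.64 ± 0.25), Nr4a3 (1.38 ± 0.19), Tgfbr1 (1.23 ± 0.19), Il7r (1.03 ± 0.13) and Irf4 (1.10 ± 0.20), a transcription factor, rose. Ifng (-1.54 ± 0.66), Tbx21 (-0.76 ± 0.48), Il4 (-0.44 ± 0.38), Gata3 (0.48 ± 0.30), Il10 (-0.82 ± 0.37), Il17a (-0.20 ± 0.18), Il2ra (0.74 ± 0.48), Ctla4 (0.00 ± 0.26), Smad3 (0.12 ± 0.26), Dhrs3 (0.49 ± 0.25), Cyp26b1 (0.04 ± 0.15), Rarb (0.04 ± 0.43) and Itgb7 (0.03 ± 0.19) did not pass.

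LP-DC over Sp-DC plus RA, Foxp3+ cells. Compared directly, Foxp3+ cells from LP-DC cultures had less Ccr9, Cyp26b1 and Dhrs3 and more Ifitm1, Ifitm2 and Ifitm3 than those from Sp-DC with RA (2 arrays in each group). Cyp26b1 (-2.68 ± 0.14, adjusted p = 6.45e-05 paired and 0.00105 unpaired) and Ccr9 (-5.44 ± 0.40, adjusted p = 0.000239 paired and 0.023 unpaired) were lower, and Ifitm1 (3.68 ± 0.23, adjusted p = 9.29e-05 paired and 0.00312 unpaired) and Ifitm3 (4.70 ± 0.53, adjusted p = 0.00256 paired and 0.0342 unpaired) higher. In all 11 genes passed unpaired, 4 higher and 7 lower, and 222 paired, 132 higher and 90 lower. Il6ra (2.88 ± 0.25) and Efna5 (1.70 ± 0.17) were also higher in both fits, and Asb2 (-2.08 ± 0.14), Cracdl (-2.49 ± 0.15), Gda (-2.66 ± 0.15), Csn2 (-2.18 ± 0.17) and Grtp1 (-1.72 ± 0.18) lower. In the paired fit Lztfl1 (-2.18 ± 0.13), Bex1 (-2.66 ± 0.25), Cd93 (-2.19 ± 0.25), Ctla2a (-2.18 ± 0.33) and Gzmc (-2.78 ± 0.39) were lower, and Ifitm2 (1.94 ± 0.31), Scin (1.93 ± 0.27), Gramd3 (1.84 ± 0.15) and Cd83 (1.45 ± 0.15) higher. Unpaired calls were 3 without either LP Foxp3+ array, 6 and 5 without SpRA Foxp3+ 1 or 2, 17 after quantile normalization, 19 after median-centring, where 47.4% were rises against 36.4%, 5 with a stricter filter, 17 over all arrays and 6 from the compared groups. Paired calls were 45 without LP Foxp3+ 2, and 92 and 52 without SpRA Foxp3+ 1 or 2.

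Interferon response genes had 4 of 17 higher and 1 lower in the paired fit and 0 unpaired (10 and 0 higher over the list alone), with Gbp2 (2.05 ± 0.16), Gbp3 (1.48 ± 0.16) and Irgm1 (0.88 ± 0.14) among them (adjusted p = 2.01e-06, adjusted p = 0.3 with an estimated correlation). Iigp1 (2.51 ± 0.22) and Gbp6 (2.01 ± 0.21), of the same family of GTPases, were higher too. Retinoid metabolism genes had 4 of 14 lower in the paired fit, Dhrs3 (-1.87 ± 0.21) among them, and 2 unpaired (adjusted p = 0.00174, adjusted p = 0.241 with an estimated correlation). The Th1 programme had 2 higher and 1 lower of 12, Il18r1 (1.83 ± 0.26), Eomes (1.81 ± 0.26) and Gzmb (-1.62 ± 0.20), and its test did not pass (adjusted p = 0.82). Tnfsf11 (-1.70 ± 0.35) was lower in the paired fit. Itga4 (-0.39 ± 0.31), Itgb7 (0.07 ± 0.19), Rarb (-0.13 ± 0.43), Ifng (0.06 ± 0.66), Tbx21 (0.32 ± 0.48), Il4 (-0.41 ± 0.38), Gata3 (0.59 ± 0.30), Il10 (-0.34 ± 0.37), Il17a (-0.18 ± 0.18), Il2ra (0.65 ± 0.48), Ctla4 (0.23 ± 0.26) and Smad3 (-0.28 ± 0.26) did not pass.

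RA over none with Sp-DC, Foxp3- cells. In Foxp3- cells (1 array with RA and 2 without) RA raised Ccr9 and lowered Ifitm1, as in Foxp3+ cells. Ifitm1 (-3.78 ± 0.30, adjusted p = 0.000776 paired and 0.03 unpaired) fell in both fits and was the only unpaired call (limma, 293 with an unadjusted p under 0.05). In the paired fit, which called 31 genes, 18 higher and 13 lower (17 and 12 of them called the same way in Foxp3+ cells), Ccr9 (4.69 ± 0.51, adjusted p = 0.0054), Cyp26b1 (1.69 ± 0.18, adjusted p = 0.0054) and Dhrs3 (2.47 ± 0.27) rose. Ccr9 read 8.46 with RA and 4.31 and 4.03 without, near background, and its same-number pair differs by 4.43. Bex1 (4.07 ± 0.32), Cttn (2.68 ± 0.35), Cracdl (2.49 ± 0.19), Grtp1 (2.10 ± 0.23), Lztfl1 (2.27 ± 0.17), Asb2 (1.87 ± 0.18), Sh3gl3 (1.89 ± 0.28) and Tmem176b (2.11 ± 0.23) rose too, and Eomes (-2.63 ± 0.33), B3gnt5 (-2.01 ± 0.31), Tmcc3 (-1.90 ± 0.28), Tubb2b (-1.62 ± 0.18) and Macir (-1.52 ± 0.23) fell. Without Sp Foxp3- 1 or 2 the unpaired count was 0 (limma, 261 and 262 with an unadjusted p under 0.05) and the paired count 8 and 4. The mean of probe sets gave 2 unpaired calls, the 17-array fit 7 and the compared groups alone 0 (limma, 275 with an unadjusted p under 0.05). Retinoid metabolism genes had 3 of 14 up in the paired fit and 0 unpaired (adjusted p = 0.00155, adjusted p = 0.217 with an estimated correlation), and the Th1 programme 1 of 12 down (adjusted p = 0.00155, adjusted p = 0.386 with an estimated correlation). Itga4 (1.85 ± 0.38), Itgb7 (0.25 ± 0.24), Rarb (-0.41 ± 0.53), Ifng (0.07 ± 0.81), Tbx21 (-1.01 ± 0.58), Il4 (-0.31 ± 0.47), Gata3 (0.24 ± 0.36), Il10 (-0.50 ± 0.46), Il17a (-0.08 ± 0.22), Il2ra (0.10 ± 0.58), Ctla4 (-0.15 ± 0.32) and Smad3 (0.91 ± 0.32) did not pass.

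LP-DC over Sp-DC, Foxp3- cells. In Foxp3- cells LP-DC lowered Mt1 and Mt2, which encode metallothioneins, Gzmb, Gzmc and the sterol synthesis genes Fdps, Mvd and Fdft1 and raised Il17a (0.94 ± 0.16, adjusted p = 0.0412), the Th17 cytokine (2 arrays in each group). Unpaired there were 0 calls (limma, 794 with an unadjusted p under 0.05), and the paired fit 102, 25 higher and 77 lower. St8sia6 (2.80 ± 0.29, adjusted p = 0.0121), a sialyltransferase, Ncoa7 (1.93 ± 0.36), Egr2 (1.58 ± 0.26), Btbd11 (1.16 ± 0.19), Adh1 (1.08 ± 0.17), an alcohol dehydrogenase, Il6ra (1.46 ± 0.25) and Il7r (1.04 ± 0.13) rose. Mt1 (-2.56 ± 0.33) and Mt2 (-2.73 ± 0.41), Emilin2 (-2.84 ± 0.48), Basp1 (-2.25 ± 0.35), Cd93 (-2.23 ± 0.25), C1qtnf12 (-2.22 ± 0.26), Cdkn1a (-2.08 ± 0.31), a cell cycle inhibitor, Crem (-1.93 ± 0.35), Gzmb (-1.89 ± 0.20, adjusted p = 0.0121), Gzmc (-2.04 ± 0.39) and Tnfrsf9 (-1.66 ± 0.25) fell. The paired count was 3 without LP Foxp3- 2, 1 without Sp Foxp3- 1 and 0 without Sp Foxp3- 2 (limma, 1116 with an unadjusted p under 0.05). It was 243 after quantile normalization, 174 with trended variances and 15 with the mean of probe sets, and the share of rises moved from 24.5% to 35.0% (quantile) and 39.6% (median-centred). Sterol and fatty acid genes had 3 of 20 down in the paired fit and 0 unpaired, Fdps (-1.29 ± 0.22), Mvd (-1.28 ± 0.16) and Fdft1 (-1.11 ± 0.17) (11 and 5 over the list alone), with a median of -0.55 (adjusted p = 1.39e-06, adjusted p = 0.267 with an estimated correlation). Glycolysis genes had 0 of 13 calls in both fits and a median of -0.37 (adjusted p = 2.61e-06, adjusted p = 0.267 with an estimated correlation). Of 9 DC markers H2-Ab1 (-1.28 ± 0.21), an MHC class II chain, was lower. Ifng (0.91 ± 0.66), Tbx21 (-0.56 ± 0.48), Il4 (-0.18 ± 0.38), Gata3 (0.19 ± 0.30), Il10 (-0.28 ± 0.37), Ctla4 (-0.46 ± 0.26), Smad3 (-0.07 ± 0.26), Dhrs3 (0.55 ± 0.25), Cyp26b1 (0.18 ± 0.15), Rarb (0.27 ± 0.43), Ccr9 (0.44 ± 0.62), Itga4 (1.31 ± 0.31), Itgb7 (0.09 ± 0.19) and Il2ra (0.06 ± 0.48), whose other probe set moved the other way, did not pass.

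LP-DC over Sp-DC plus RA, Foxp3- cells. Foxp3- cells from LP-DC cultures had less Gzmb, Gzmc, Ccr9 and Cyp26b1 than those from Sp-DC with RA (2 arrays against 1). The unpaired fit called 0 genes (limma, 736 with an unadjusted p under 0.05), and the paired fit 62, 22 higher and 40 lower. Ccr9 (-4.25 ± 0.51, adjusted p = 0.00833), Gzmc (-4.01 ± 0.49, adjusted p = 0.00833), Bex1 (-2.92 ± 0.32), Cracdl (-2.58 ± 0.19), Igsf5 (-2.54 ± 0.30), Selenbp1 (-2.44 ± 0.39), Lztfl1 (-2.42 ± 0.17), P4ha2 (-2.26 ± 0.38), Nrn1 (-2.21 ± 0.31), Gzmb (-1.95 ± 0.25) and Ebi3 (-1.86 ± 0.23) were lower. Ms4a4c (3.28 ± 0.36, adjusted p = 0.00679), Ifitm1 (2.55 ± 0.30), Il18r1 (2.19 ± 0.32), Il6ra (2.16 ± 0.31), B3gnt5 (2.04 ± 0.31), Iigp1 (1.96 ± 0.28), Gramd3 (1.96 ± 0.19), Klrd1 (1.78 ± 0.30) and Cldnd1 (1.62 ± 0.22) were higher. Paired counts were 93 without LP Foxp3- 1, 15 without LP Foxp3- 2 and 38 with the mean of probe sets, and unpaired counts 1 after median-centring and 3 over all arrays. Retinoid metabolism genes had 3 of 14 lower in the paired fit and 0 unpaired, Cyp26b1 (-1.51 ± 0.18), Dhrs3 (-1.92 ± 0.27) and Asb2 (-1.93 ± 0.18) (adjusted p = 0.00744, adjusted p = 0.28 with an estimated correlation). The DC marker H2-Ab1 (-1.47 ± 0.26) was lower. Itga4 (-0.54 ± 0.38), Itgb7 (-0.17 ± 0.24), Rarb (0.69 ± 0.53), Ifng (0.83 ± 0.81), Tbx21 (0.45 ± 0.58), Il4 (0.12 ± 0.47), Gata3 (-0.05 ± 0.36), Il10 (0.22 ± 0.46), Il17a (1.02 ± 0.22), Il2ra (-0.04 ± 0.58), Ctla4 (-0.31 ± 0.32) and Smad3 (-0.98 ± 0.32) did not pass.

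Interactions. No gene passed for the RA effect in Foxp3+ against Foxp3- cells (limma, 55 with an unadjusted p under 0.05 unpaired and 231 paired, 0 adjusted), nor for the LP-DC effect (108 and 434, 0 adjusted in each fit), so genes called in one sort and not in the other are not shown to differ. The paired LP-DC interaction had 1 call with trended variances and 3 without LP Foxp3+ 1. The LP-DC effect on the regulatory T cell signature was higher in Foxp3+ than in Foxp3- cells (median 0.42, adjusted p = 2.93e-05, adjusted p = 0.139 with an estimated correlation), and that on the cell cycle list lower (median -0.28, adjusted p = 3.43e-06, adjusted p = 0.539 with an estimated correlation). It was lower too for effector cytokines and chemokines (median -0.26, adjusted p = 0.000328), genes lower in Foxp3-expressing T cells (-0.34, adjusted p = 0.00069) and CD8 T and NK markers (-0.64, adjusted p = 0.0012), with 0.111, 0.111 and 0.152 for an estimated correlation. For RA the co-stimulatory receptors had a median of -0.36 (adjusted p = 0.0269) and the cell cycle list 0.15 (adjusted p = 0.0075), both with adjusted p = 0.575 for an estimated correlation.

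**Figure D4:**
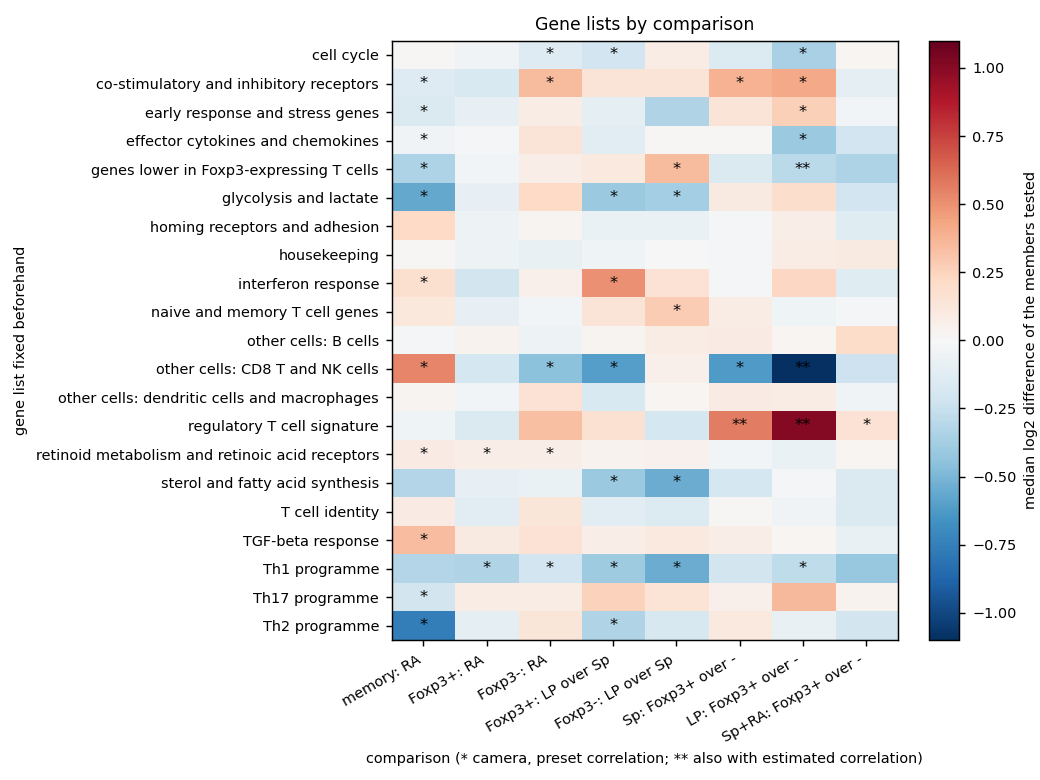
Median log2 difference of 21 gene lists (vertical) in 8 comparisons (horizontal), unpaired fit; 1 asterisk marks a list that passed with the preset correlation and a double asterisk one that also passed with an estimated correlation. The regulatory T cell signature has medians of 0.56 with Sp-DC, 1.01 with LP-DC and 0.16 with Sp-DC plus RA.

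Shared and separate effects. Across genes, which are not independent, the RA effects in Foxp3+ and Foxp3- cells correlated at 0.52 (0.65 in the paired fit), the LP-DC effects in both sorts at 0.71, and the Foxp3+ over Foxp3- differences with Sp-DC and with LP-DC at 0.67. In the last, 30 genes rose in both paired fits (0.767 by chance) and 30 fell in both (0.402 by chance), Ecm1, Gpr83, Cd81, Enah, Izumo1r among the rises. The RA effects in memory and in Foxp3+ cells correlated at 0.30 (leave-one-out SD 0.050, from 0.17 without MemoryRA 3). In the paired fits 33 genes rose in both, Itga4, Ccr9, Cyp26b1, Dhrs3, Hic1, Asb2 and Lztfl1 among them (1.71 by chance), 13 fell in both (1.27 by chance) and 2 moved in opposite directions. With Foxp3- cells the correlation was 0.20 (leave-one-out SD 0.080, 0.05 without Sp Foxp3- 2 and 0.33 without Sp Foxp3- 1). Of the genes RA raised in memory cells in the paired fit, 70.0% were higher with RA in Foxp3+ cells, against 49.8% of all genes, and of those it lowered 75.7% were lower, against 50.2%. With RA in Foxp3- cells the shares were 72.1% (53.5% of all) and 63.1% (46.5%). LP-DC without added RA gave 61.3% (51.5%) and 65.4% (48.5%) in Foxp3+ cells and 63.6% (49.0%) and 77.2% (51.0%) in Foxp3- cells. Whether the shares differ between RA and LP-DC was not tested.

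The LP-DC and RA effects in Foxp3+ cells correlated at 0.51 (leave-one-out SD 0.134, 0.37 without SpRA Foxp3+ 1 and 0.73 without Sp Foxp3+ 1). They share the Sp-DC arrays, and noise alone gave 0.49 in data simulated for the unpaired and 0.50 for the paired fit. The covariance was 0.054, against 0.046 and 0.018 for noise alone, which leaves 0.008 unpaired and 0.036 paired as the estimate of a shared effect. In Foxp3- cells, with 1 array with RA, the correlation was 0.19 unpaired and 0.35 paired, against 0.41 and 0.40 for noise alone. The covariance there exceeded that of noise by -0.028 unpaired, with the same limit, and 0.017 paired. In the paired fits 11 genes rose in both, Itga4 and Egr2 among them, 13 fell in both, with Endou, Lgals3 and Maf, and 3 moved in opposite directions. Independent lists would share 0.857 and 0.385. These values leave out the shared arrays, from which part of the overlap can come. With no array in common, LP-DC in Foxp3- cells against RA in Foxp3+ cells gave 0.36, and LP-DC in Foxp3+ cells against RA in Foxp3- cells gave 0.22. The same-numbered Sp-DC arrays of both sorts deviate together (correlation 0.75), so noise of the controls is not independent in these values, nor in those above that compare the sorts. In a paired joint fit the RA effect differed between memory and Foxp3+ cells for 161 genes (96 with a higher signed log2 difference in memory, 65 lower). Against Foxp3- cells it differed for 79, 49 higher and 30 lower. Cell type, time, partner cells and RNA quality differ together in that contrast.

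**Figure D5:**
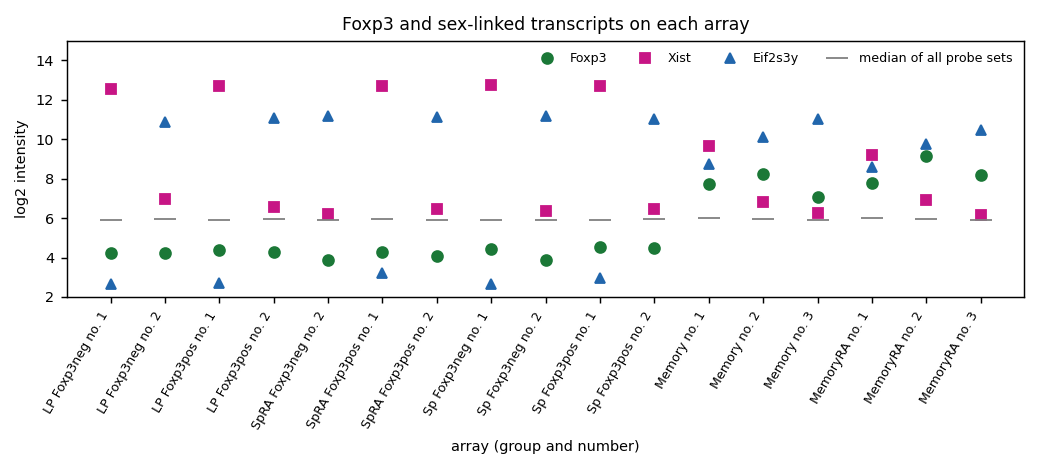
Log2 signal of Foxp3, Xist and Eif2s3y and the array median (y axes) on each of the 17 arrays (x axis), by group. Xist lies between 12.54 and 12.74 on the co-culture arrays numbered 1 and between 6.22 and 6.99 on those numbered 2.

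Array quality. Arrays of 1 group correlated at 0.923 to 0.989. The Foxp3 probe set read 7.08 to 9.14 in memory cells. The memory arrays numbered 3 stand apart, with interquartile ranges of 3.03 and 3.07 against 2.53 to 2.66 in the others. The co-culture arrays differ by number, with Xist high and Y-linked genes low on number 1 and the reverse on 2. The Actb 3-prime minus 5-prime value is 1.80 to 2.18 on number 1 and 2.72 to 2.97 on number 2. On memory arrays it is higher (3.54 to 4.08), as is that of Gapdh. Both Sp-DC arrays numbered 2, controls of the RA and LP-DC comparisons, read 10.44 and 9.36 for the heat-shock gene Hspa1a and 11.06 and 10.36 for Hspa1b, against 3.69 to 4.65 and 5.44 to 6.85 on the other co-culture arrays. Both genes were chosen after their values were seen. Few arrays limit the precision of every comparison.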

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

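Tests of the sex genes on X and Y, of the Foxp3 probe set and of the cytotoxic markers were chosen only after the results had been seen, except the share of genes on X and Y, the genes that escape X inactivation and the exchanged labels. Among the last, the count over relabellings that part every pair was set against the real one after it had been seen.

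RA acted differently in memory and in co-culture cells for 161 genes against Foxp3+ and 79 against Foxp3- cells. Values are signed log2 differences, memory minus co-culture effect, so a positive one can also come from a smaller fall in memory cells. Among the 31 genes listed here against Foxp3+ cells, it was positive for Ifitm1 (3.81), Nkg7 (2.89), Endou (2.44), Klrd1 (2.29), Gfi1 (2.15), Eomes (2.05), Itga4 (1.95), Nrip1 (1.82), Fam102b (1.81), Ifitm2 (1.75), Tmcc3 (1.62), Hic1 (1.54), Jun (1.28), Nipal1 (1.20) and Stat4 (1.08). It was negative for Bex1 (-4.25), Gda (-3.17), Il10 (-2.36), Ndrg1 (-2.36), Egr3 (-2.19), Atf3 (-2.16), Il4 (-1.96), Ddit4 (-1.73), Tnfsf14 (-1.73), Egr2 (-1.66), Satb1 (-1.65), Aldoc (-1.55), Cttn (-1.55), Ahr (-1.26), Cyp26b1 (-1.23) and Asb2 (-1.14). Against Foxp3- cells, 18 genes are listed. The difference was positive for Ifitm1 (3.16), Klrd1 (2.52), Eomes (2.46), Gfi1 (2.35), Nkg7 (2.29), Itga4 (2.10), Fam102b (1.89) and Hic1 (1.78). It was negative for Bex1 (-4.84), Ndrg1 (-2.85), Aldoc (-2.37), Il10 (-2.15), Atf3 (-2.09), Tnfsf14 (-2.02), Il4 (-1.98), Ddit4 (-1.96), Satb1 (-1.62) and Gda (-1.47). The experiments differ in cell type, time, TGF-beta dose, partner cells and RNA quality at once, and which acts was not tested.

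Xist was high and Y-linked genes were low on all co-culture arrays numbered 1, although the labels give male mice. The lowest Xist value there exceeds the highest on number 2 by 5.55. Gaps of 7.65 for Eif2s3y, 3.38 for Kdm5d and 2.71 for Uty go the other way. These Y-linked genes lay at or under 5.17 on number 1, below array medians, which argues against all-male pools. Dim Y-linked probe sets alone are excluded, because Xist itself is 6.17 higher on average. Genes that escape X inactivation could not tell, with a median of 0.50 over 4 genes, where Kdm6a (1.13, adjusted p = 0.000466) and Eif2s3x (0.95, adjusted p = 0.000374) were higher and Kdm5c (0.05) and Ddx3x (0.05) were not. The memory arrays numbered 1 lie between, with Xist at 9.64 and 9.21 against 6.14 to 6.90 on the other memory arrays and Eif2s3y at 8.74 and 8.61 against 9.75 to 11.02. The mice may have been of both sexes. Each number occurs in every group but SpRA Foxp3-, so sex is balanced over comparisons without that group.

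Between the numbers 3960 genes differed, 2869 higher and 1091 lower on number 2. Their share on X or Y is 0.036 against 0.030 of all genes tested, but Xist follows the number, so sex stays open. The Actb 3-prime minus 5-prime value, a sign of RNA quality, is higher on number 2 (2.72 to 2.97 against 1.80 to 2.18). That of Gapdh overlaps and is lower there (mean 2.68 against 3.13). Days, mice, RNA quality or amplification may be behind the number effect, and no label tells these apart.

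The Foxp3 probe set was near background on all 11 co-culture arrays, Foxp3+ (mean 4.34, SD 0.16) and Foxp3- (4.13, SD 0.25) alike. With Sp-DC and LP-DC the regulatory T cell list without Foxp3 is higher in Foxp3+ cells, with 0.56 the lower median. This argues against exchanged sort labels there. With an estimated correlation it passed only unpaired (camera adjusted p = 0.0362 and 0.0181, against 0.177 and 0.122 paired). With Sp-DC plus RA, where 1 Foxp3- array was measured, the median is 0.16 unpaired and 0.32 paired, which cannot tell. A probe set unable to detect Foxp3 is excluded, because it lies at least 1.20 above the array median in memory cells. A reporter allele that changes the transcript where the probe set binds may be the reason, but the highest co-culture value of -1.39 against the array median cannot tell this from a difference between the experiments. The 5 Foxp3+ samples whose source name says Foxp3- are taken by their sort label.

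Gzma, Klrd1 and Cxcr6 were higher in Foxp3- cells. CD8 T or NK cells in that fraction could be the source, but of Cd8b1, Ncr1, Prf1 and Nkg7 the lowest Foxp3- minus Foxp3+ difference was -0.12 and that of Nkg7 0.46 ± 0.22, so the test cannot tell. Cd8a goes with it in the LP-DC culture (-1.26 ± 0.24, passed in the paired fit) but did not pass over the mean of the cultures. The labels name CD4 T cells, a selection that would remove such cells. Cd8b1, Ncr1 and Prf1 lay below the array median on all 5 Foxp3- arrays, and Nkg7 above it. RNA quality may differ between the fractions. The Actb 3-prime minus 5-prime value was lower in Foxp3+ cells in all 5 pairs, with differences from -0.33 to -0.01, smaller than the median SD between numbers of 0.55. That of Gapdh was lower in 4 of the 5, with -0.90 in the Sp-DC pair numbered 2 the farthest from 0. This explanation stays open.

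Exchanged labels. For RA in memory cells the real grouping called 10 genes unpaired and 596 paired, and the highest other count was 0 among 10 splits unpaired and among the 4 that part every pair when paired (limma). These are too few to exclude chance. For the mean Foxp3+ difference 5 of 100 relabellings, the real one included, called at least as many as the real 109, so chance cannot be excluded where the pairing is ignored. The highest other count was 4622, many times the real one, which points to a structure of the samples. That one parts 0 of the 5 same-number pairs and so follows the array number within each culture. Of the 30 relabellings that part every pair, only the real one called as many. The highest other was 28 unpaired, and 389 against 568 paired. Compared after the count was seen, these do not exclude chance.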

How the results depend on the processing

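Both memory arrays numbered 3 left out, and the settings repeated under the block, were chosen only after results had been seen.

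Counts of changed genes. The array number as a block was the alternative that moved the results furthest, and which of the possible causes acts was not tested. It took RA in memory cells from 10 calls to 596, the mean Foxp3+ over Foxp3- difference from 109 to 568, Foxp3+ over Foxp3- from 0 to 66 with Sp-DC, from 16 to 424 with LP-DC and from 0 to 3 with Sp-DC plus RA. RA over none went from 12 to 133 in Foxp3+ and from 1 to 31 in Foxp3- cells. LP-DC over Sp-DC went from 0 to 215 and from 0 to 102, and LP-DC over Sp-DC plus RA from 11 to 222 and from 0 to 62. All planned calls are among those of the paired fit.

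Other settings changed counts as follows, and the cause was not tested. Quantile normalization gave 48 calls for Foxp3+ over Foxp3- with LP-DC and 17 for LP-DC over Sp-DC plus RA in Foxp3+ cells. Arrays centred on the median of the genes tested gave 164 for the mean Foxp3+ difference, 39 for it with LP-DC, and 19 and 1 for LP-DC over Sp-DC plus RA in Foxp3+ and Foxp3- cells. A stricter filter gave 6 calls for RA in memory cells, 6 for RA in Foxp3+ cells and 5 for LP-DC over Sp-DC plus RA. The mean of all probe sets gave 37 for Foxp3+ over Foxp3- with LP-DC and 2 for RA in Foxp3- cells. Log2 of the value plus 32 gave 2 calls for Foxp3+ over Foxp3- with Sp-DC plus RA.

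One fit over all 17 arrays gave 78 calls for RA in memory cells, 1 for Foxp3+ over Foxp3- with Sp-DC plus RA, 20 and 7 for RA in Foxp3+ and Foxp3- cells, and 17 and 3 for LP-DC over Sp-DC plus RA. A fit to only the groups compared gave 0 for Foxp3+ over Foxp3- with LP-DC (limma, 771 with an unadjusted p under 0.05), 3 and 0 for RA in Foxp3+ and Foxp3- cells (limma, 275 with an unadjusted p under 0.05 for the latter) and 6 for LP-DC over Sp-DC plus RA in Foxp3+ cells. With both memory arrays numbered 3 left out, 202 genes were called, 114 higher and 88 lower, and they include all 10 of the planned fit. Under the block 208 were called, 206 of them among the 596. The median log2 difference moved by more than 0.1 under a scaling only for LP-DC over Sp-DC plus RA in Foxp3- cells, from -0.06 to 0.08 after median-centring.

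Under the block, leaving out genes on X and Y gave 552 calls for the mean Foxp3+ difference, 73 with Sp-DC and 415 with LP-DC, 127 and 26 for RA in Foxp3+ and Foxp3- cells, 170 and 99 for LP-DC over Sp-DC, and 214 and 59 for LP-DC over Sp-DC plus RA.

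Other settings repeated under the block moved these counts. Quantile normalization gave 112 calls for Foxp3+ over Foxp3- with Sp-DC, 418 for LP-DC over Sp-DC in Foxp3+ cells and 243 in Foxp3- cells. The mean of all probe sets gave 10, 36 and 15 in the same order, 38 for LP-DC over Sp-DC plus RA in Foxp3- cells and 1 for Foxp3+ over Foxp3- with Sp-DC plus RA. With 1 array left out the paired counts ranged from 208 to 819 for RA in memory cells, from 329 to 594 for the mean Foxp3+ difference, from 1 to 60 with Sp-DC, from 168 to 305 with LP-DC, from 48 to 129 for RA in Foxp3+ cells, from 2 to 451 for LP-DC over Sp-DC in Foxp3+ cells, from 0 to 85 in Foxp3- cells (limma, 1116 with an unadjusted p under 0.05 at 0), and from 45 to 198 for LP-DC over Sp-DC plus RA in Foxp3+ cells.

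Leaving out 1 array. RA in memory cells ranged from 0 calls without Memory 2 (limma, 330 with an unadjusted p under 0.05) to 7 without Memory 3, and the mean Foxp3+ difference from 3 without Sp Foxp3- 1 to 99 without Sp Foxp3+ 2. Foxp3+ over Foxp3- with LP-DC ranged from 0 without LP Foxp3+ 1 (limma, 556 with an unadjusted p under 0.05) to 3 without LP Foxp3- 2. RA in Foxp3+ cells ranged from 6 without Sp Foxp3+ 2 to 12 without Sp Foxp3+ 1, and LP-DC over Sp-DC plus RA in Foxp3+ cells from 3 to 6. RA in Foxp3- cells had 0 calls without either Sp Foxp3- array (limma, 261 and 262 with an unadjusted p under 0.05).

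The correlation of the LP-DC and RA effects in Foxp3+ cells ranged from 0.37 to 0.73. That of RA in memory and Foxp3+ cells ranged from 0.17 without MemoryRA 3 to 0.31 without MemoryRA 1.

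Named genes. Of 9259 values compared for the 667 gene results the rule names, 8337 were the same, 368 weaker, 437 stronger and 117 reversed, the last in 62 gene results. None of the 75 results called unpaired was reversed, and 1 of the 413 called paired was, Id2 in memory cells, at -0.02 without MemoryRA 3 and 1.08 without Memory 3 (planned value 0.55). For the 422 named in the text the counts are 5119 the same, 344 weaker, 305 stronger and 113 reversed.

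Reversals under settings other than left-out arrays concern genes that did not pass. Under the block Ccr9 and Rarb in the mean Foxp3+ difference were -0.13 and -0.02 (0.00 and 0.09 as planned). With Sp-DC plus RA, Gata3 and Il17a were 0.17 and -0.01 (-0.02 and 0.01). In LP-DC over Sp-DC plus RA, Foxp3- cells, Gata3, Il2ra and Il4 were 0.14, 0.12 and -0.17 (-0.05, -0.04 and 0.12). RA in Foxp3- cells gave -0.39 for Ifng and -0.06 for Il2ra (0.07 and 0.10). Under median-centring Il10 and Rarb in Foxp3+ over Foxp3- with Sp-DC were 0.04 and 0.03 (0.00 and -0.02), Gata3 with Sp-DC plus RA 0.06, Gata3 and Il2ra in LP-DC over Sp-DC plus RA, Foxp3- cells, 0.08 and 0.10, and Ifng under RA in Foxp3- cells -0.01. Quantile normalization gave 0.06 for Gata3 with Sp-DC plus RA, 0.06 for Ctla4 under LP-DC in Foxp3+ cells (0.00), 0.05 and 0.07 for Gata3 and Il2ra in LP-DC over Sp-DC plus RA, Foxp3- cells, and 0.01 for Il17a under RA in Foxp3+ cells (-0.02). The mean of all probe sets gave 0.14 for Ccr9 and -0.01 for Smad3 in Foxp3+ over Foxp3- with Sp-DC (-0.13 and 0.24), -0.32 for Il2ra under LP-DC in Foxp3- cells (0.06), 0.00 for Ccr9 under LP-DC in Foxp3+ cells (-0.15) and -0.01 for Smad3 in memory cells (0.22).

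The ranges over left-out arrays of genes with a reversal follow, planned log2 difference in parentheses. Apart from Id2 none of these genes passed. In memory cells given RA, Ctla4 (-0.04) from -1.31 to 1.31, Id2 (0.55) from -0.02 to 1.08 and Rarb (-0.14) from -0.46 to 0.10. For Foxp3+ over Foxp3- cells over the mean of the cultures, Ccr9 (0.00) from -0.35 to 0.36, Il10 (-0.17) from -0.36 to 0.01, Itgb7 (0.01) from -0.06 to 0.08 and Rarb (0.09) from -0.12 to 0.30. In Foxp3+ over Foxp3- cells with Sp-DC, Ccr9 (-0.13) from -0.27 to 0.01, Cyp26b1 (0.04) from -0.03 to 0.12, Ifng (0.42) from -0.37 to 1.21 and Il10 (0.00) from -0.57 to 0.56. Further, Il17a (-0.06) from -0.23 to 0.11, Itga4 (0.21) from -0.21 to 0.64, Itgb7 (0.12) from -0.08 to 0.33 and Rarb (-0.02) from -0.32 to 0.28. For Foxp3+ over Foxp3- cells with LP-DC, Itgb7 (0.07) from -0.01 to 0.15 and Rarb (-0.26) from -0.63 to 0.12. In Foxp3+ over Foxp3- cells with Sp-DC plus RA, Ccr9 (0.87) from -0.18 to 1.93, Gata3 (-0.02) from -0.41 to 0.36 and Il10 (0.02) from -0.23 to 0.28. Likewise, Il17a (0.01) from -0.14 to 0.16, Itgb7 (-0.17) from -0.35 to 0.01 and Rarb (0.55) from -0.07 to 1.18. For RA in Foxp3+ cells, Gata3 (-0.11) from -0.50 to 0.28, Il17a (-0.02) from -0.17 to 0.14 and Il2ra (0.09) from -0.33 to 0.51. Further, Il4 (-0.03) from -0.33 to 0.27, Itgb7 (-0.04) from -0.22 to 0.14 and Rarb (0.16) from -0.47 to 0.79.

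In RA in Foxp3- cells, Ifng (0.07) from -0.72 to 0.86, Il10 (-0.50) from -1.07 to 0.06, Il17a (-0.08) from -0.25 to 0.09, Il2ra (0.10) from -0.10 to 0.29 and Il4 (-0.31) from -0.85 to 0.23. For LP-DC over Sp-DC in Foxp3+ cells, Ctla4 (0.00) from -0.16 to 0.15, Cyp26b1 (0.04) from -0.02 to 0.10, Itgb7 (0.03) from -0.07 to 0.13, Rarb (0.04) from -0.17 to 0.25 and Smad3 (0.12) from -0.15 to 0.38. In LP-DC over Sp-DC in Foxp3- cells, Ccr9 (0.44) from -0.15 to 1.04, Gata3 (0.19) from -0.15 to 0.52, Il10 (-0.28) from -0.84 to 0.28 and Il2ra (0.06) from -0.73 to 0.84. Further, Il4 (-0.18) from -0.72 to 0.36, Itgb7 (0.09) from -0.12 to 0.29, Rarb (0.27) from -0.10 to 0.64 and Smad3 (-0.07) from -0.26 to 0.13. For LP-DC over Sp-DC plus RA in Foxp3+ cells, Ifng (0.06) from -0.12 to 0.25, Itgb7 (0.07) from -0.11 to 0.25, Rarb (-0.13) from -0.75 to 0.50 and Tbx21 (0.32) from -0.32 to 0.97. In LP-DC over Sp-DC plus RA in Foxp3- cells, Ctla4 (-0.31) from -0.73 to 0.10, Gata3 (-0.05) from -0.39 to 0.28, Il2ra (-0.04) from -0.82 to 0.74 and Il4 (0.12) from -0.20 to 0.45.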

Other observations

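Tests of hypoxia-inducible and amino acid response genes were set up after the list results were seen. Trib3 and Ddit3 (early response list) and Fam162a and P4ha2 (falls shared with LP-DC) were in earlier results.

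RA lowered hypoxia-inducible genes in memory cells, next to the glycolysis list (camera, estimated correlation, p = 0.00939, adjusted p = 0.0689). Of 17 measured hypoxia-inducible genes outside the glycolysis list, 11 fell in the paired fit and 0 in the unpaired fit (limma, 495 of all genes with an unadjusted p under 0.05). They include Vegfa, Pdk1, the oxygen sensors Egln1 and Egln3, and Ero1a (-1.29). The median was -0.64, with unadjusted camera p = 2.02e-15 (preset correlation) and 0.00154 (estimated, 0.0142 paired). Lower expression of hypoxia-inducible genes fits, and lower activity of the factor that drives them may be part of the RA effect. A lower density or lower oxygen use of these cultures could give the same picture, and reporter or protein data would be needed to tell.

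Of 18 measured amino acid response genes, 7 fell in the paired fit and 0 in the unpaired fit (limma, 495 of all genes with an unadjusted p under 0.05). Trib3, Chac1, Mthfd2, the amino acid transporter Slc7a5 (-1.06) and its partner Slc3a2 are among them. The median was -0.40, with camera p = 5.63e-09 and p = 0.00323 with an estimated correlation. Without Trib3 and Ddit3, 6 of 16 fell in the paired fit and the median was -0.40 (camera p = 2.32e-07, and p = 0.00516 with an estimated correlation). Lower expression of amino acid response genes fits and may go with the fall of Cth and Atf3, but a milder amino acid shortage in the medium would look the same.

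Taking memory and co-culture cells side by side, RA raised Ccr9, Itga4, Dhrs3 and Cyp26b1 in memory and Foxp3+ cells, and Ccr9, Dhrs3 and Cyp26b1 in Foxp3- cells too, where 1 array had RA and Itga4 did not pass. It lowered Il4, Il9, Il10 and Il21 in memory cells. In the co-culture Il4 and Il10 did not pass, and Il9 and Il21 lay at or under 5.47 and 5.64, below the array medians, and were not tested. The fall of Th2 cytokines in CD44hi cells may bear on the induction of Foxp3 in the naive cells cultured with them, because IL-4 is known to oppose that induction. Those naive cells were not measured. The RA effects of memory cells correlated at 0.30 with those of Foxp3+ cells, where 33 genes rose in both paired fits (1.71 by chance). With Foxp3- cells the correlation was 0.20, from 0.05 without Sp Foxp3- 2 to 0.33 without Sp Foxp3- 1, and 0.30 under the block, where 13 rose in both (0.442 by chance).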
